A study of Rattus norvegicus with 6 samples.

How the data were processed

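Total RNA from the mesenterial fat of newborn rats was hybridised, as biotin-labelled material, to 6 Affymetrix Rat Genome 230 2.0 arrays, 3 for each maternal diet. The deposited values are linear intensity signals, and the submitters' processing notes name MAS5 and Affymetrix Expression Console, without versions. MAS5 condenses the probes of a probe set to a single signal and scales every array to a common level. The deposited signals have a 2% trimmed mean of 500 on each of the 6 arrays, as computed from the values, so differences in total RNA between arrays are removed before the values are read. Background settings, detection calls and the scaling target are not given in the sources used here. Scaled MAS5 signals of dim probe sets vary strongly on the log scale, and a ratio between arrays is only as good as the scaling.

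The table held 31099 probe sets and no missing values, and no array was a copy of another (0 identical columns). The 57 control probe sets were left out of the tests and used for quality measures. The remaining 31042 signals were log2 transformed with no offset. Probe sets with a mean log2 signal over all 6 arrays under the 40th percentile (6.46, a signal of 88.2) were not tested, which left 18625. The platform annotation names 1 gene for 20826 probe sets, several for 436 and none for 9780. Of the probe sets with 1 gene, 20758 were matched by Entrez identifier to a rat gene table of the GRCr8 assembly, which changed 0 symbols. No gene was named from a probe set with several symbols. That table's genomic gene lengths were used in a check of length, and no coordinates were taken from it, since the array values name no build.

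Groups and replicate numbers were taken from the sample titles. The design, the alternatives, 34 gene lists and the rule for named genes were set before the data were examined. The comparison was deficient minus adequate, fitted per probe set with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. Gene lists used the brightest tested probe set of each gene and were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 3 tested members. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction or in either, were run beside it. The lists held 777 genes, of which 696 had a probe set named here. Members of each list were also adjusted over the list alone. Quality measures per array were compared with exact two-sided permutation tests, whose smallest p with 3 against 3 arrays is 0.1.

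The named genes were up to 12 higher and 12 lower genes past the adjusted threshold without overlap between the groups, with open places filled by the smallest unadjusted p among tested probe sets without overlap. All 24 places were filled in that second way, so none of these genes passed. In each list described, up to 4 members with the smallest unadjusted p were named. A further 13 genes were fixed by name, and 12 of them are reported; the other is not analysed here. Members past the adjustment over their list alone, members named for going against their list (Sc5d, Acta2, Des) and genes named from single arrays in the closing section were named after their values were seen.

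The limma and camera steps were tested on simulated data for this comparison, with 200 of 18625 probe sets changed. At a log2 change of 1, 62% of the changed probe sets were recovered, and at a log2 change of 2, 100%. There were 5 false calls with changes present and 0 with no change simulated. The simulated noise was independent between probe sets and arrays. These rates therefore do not cover correlated genes or shifts shared by whole arrays. The alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, an offset of 50, eBayes without a trend, robust eBayes, array weights, the replicate number as a block, leaving out each array, an estimated inter-gene correlation, the mean of a gene's probe sets, and the 3' over middle ratio for RNA quality. Alternatives added later were deficient array 3 alone against the adequate arrays, a term for the other pair of deficient arrays, the hybridisation controls as a covariate, a term for the array without Y-linked signal, and removal of each array's trend with gene length by lowess. The term for the array without Y-linked signal, called the sex term, marks adequate array 1 alone. It gives the same log2 changes as leaving that array out. Figures were drawn with matplotlib 3.10.9.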

Results

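Mesenterial adipose tissue, the fat in the folds that carry the vessels of the gut, was profiled in newborn Sprague-Dawley rats, an outbred laboratory strain. Their dams had received feed with 1000 IU of vitamin D per kg (adequate group, 3 arrays) or with 0 IU per kg (deficient group, 3 arrays). The 18625 probe sets bright enough to test covered 10591 named genes. The median signal per array ranged from 155 to 166 intensity units. Pearson's r between arrays, across tested probe sets that are not independent replicates, ranged from 0.931 to 0.975. The labels give neither litter nor sex and do not say whether the arrays of a group are separate animals, so p-values may measure only the spread between these samples. The number of arrays limits the precision of every value below.

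The comparison asks whether gene expression in the newborns' fat differed with the vitamin D content of the dams' feed. Genes of cholesterol synthesis and uptake, of hypoxia and glycolysis, and markers of lymphocytes were lower as groups in the deficient group, and smooth muscle markers were higher. These were 4 of the 32 gene lists tested, by camera with a preset correlation. With an estimated inter-gene correlation 0 lists passed, and each of these 4 had an adjusted p of 0.780. No individual gene passed the adjusted threshold. With limma, 0 of 18625 probe sets did, and the smallest adjusted p was 0.344. At an unadjusted p under 0.05 there were 2647 probe sets, 1123 higher and 1524 lower, where chance gives 931. That number ranged from 906 without deficient array 2 to 6572 without deficient array 3. The groups did not overlap for 3235 probe sets, 17.4%, where chance gives 10%. The count past the adjusted threshold was 3614 without deficient array 3. Each of the 10 ways to split the 6 arrays into 3 and 3 gave between 3 and 8 lists past the preset-correlation threshold.

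Deficient arrays 1 and 2 stood apart from the other 4 arrays. The first principal component, with 49.5% of the variance, placed them at 43.1 and 46.4 and the others between -26.2 and -18.5. Their bacterial hybridisation controls, which are added in fixed amounts, read 7.19 and 10.1 times the mean of the adequate arrays, against 0.960 on deficient array 3. The beta-actin 3' over 5' ratio, a measure of RNA integrity and labelling, was 7.56 and 6.80 on these arrays, 2.35 on deficient array 3, and 2.39, 4.81 and 2.58 on the adequate arrays. Between the groups the log2 beta-actin ratio was 1.63 ± 0.55 (SD, n = 3) in the adequate and 2.31 ± 0.93 (SD, n = 3) in the deficient group, an exact two-sided permutation p of 0.4. The log2 Gapdh ratio was 0.27 ± 0.11 and 0.45 ± 0.32 (SD, n = 3 each), an exact permutation p of 0.5, and the log2 hybridisation controls were 8.75 ± 0.35 and 10.80 ± 1.84 (SD, n = 3 each), an exact permutation p of 0.3.

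**Figure D1:**
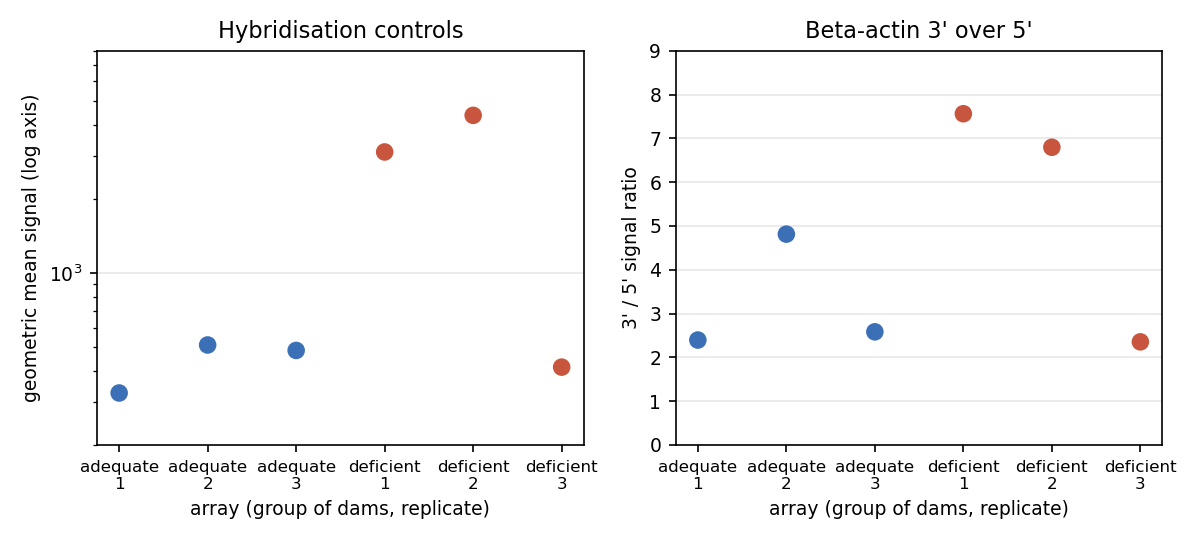
Signal of the bacterial hybridisation controls (left, geometric mean in intensity units, log axis) and the beta-actin 3' over 5' signal ratio (right) on each of the 6 arrays, 1 point per array, blue for adequate and red for deficient. Deficient arrays 1 and 2 lie at 3102 and 4370 for the controls and at 7.56 and 6.80 for the ratio, above the other 4 arrays in both panels.

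Genes of cholesterol synthesis and uptake fell by a mean of 0.47 on the log2 scale, a fold of 0.720, and 19 of the 20 tested members had lower values. Acat2, a cytosolic thiolase at the start of the pathway, had a log2 change of -0.69 ± 0.17 (SE). Mvd, which makes isopentenyl diphosphate, had -0.95 ± 0.26, Fdps, which makes farnesyl diphosphate, -0.50 ± 0.16, and Lss, which closes the sterol ring to lanosterol, -0.56 ± 0.18. None of the members passed over all probe sets, and 9 did adjusted over the list alone: these 4, Ebp, Fdft1, Pmvk, Dhcr7 and Srebf2, the transcription factor that drives the pathway, at -0.57 ± 0.19. That count was 0 after quantile normalization, with the length trend removed, and without adequate array 1, adequate array 3 or deficient array 2, 0 also with a term for deficient arrays 1 and 2, with deficient array 3 alone, with the hybridisation controls as a covariate and with a sex term, and 2 without a variance trend. Only Sc5d had a higher value in the deficient group, 0.10. The list passed camera with an adjusted p of 5.98e-05, and had an adjusted p of 0.780 with an estimated correlation and of 0.247 with fry. The list mean was 0.16, -0.20 and 0.04 on the adequate arrays and -0.27, -0.71 and -0.44 on the deficient arrays, relative to the adequate mean, so the groups did not overlap. A regrouping of the arrays that mixed the diets gave this list a smaller unadjusted camera p, 8.39e-10 against 1.87e-06.

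**Figure D2:**
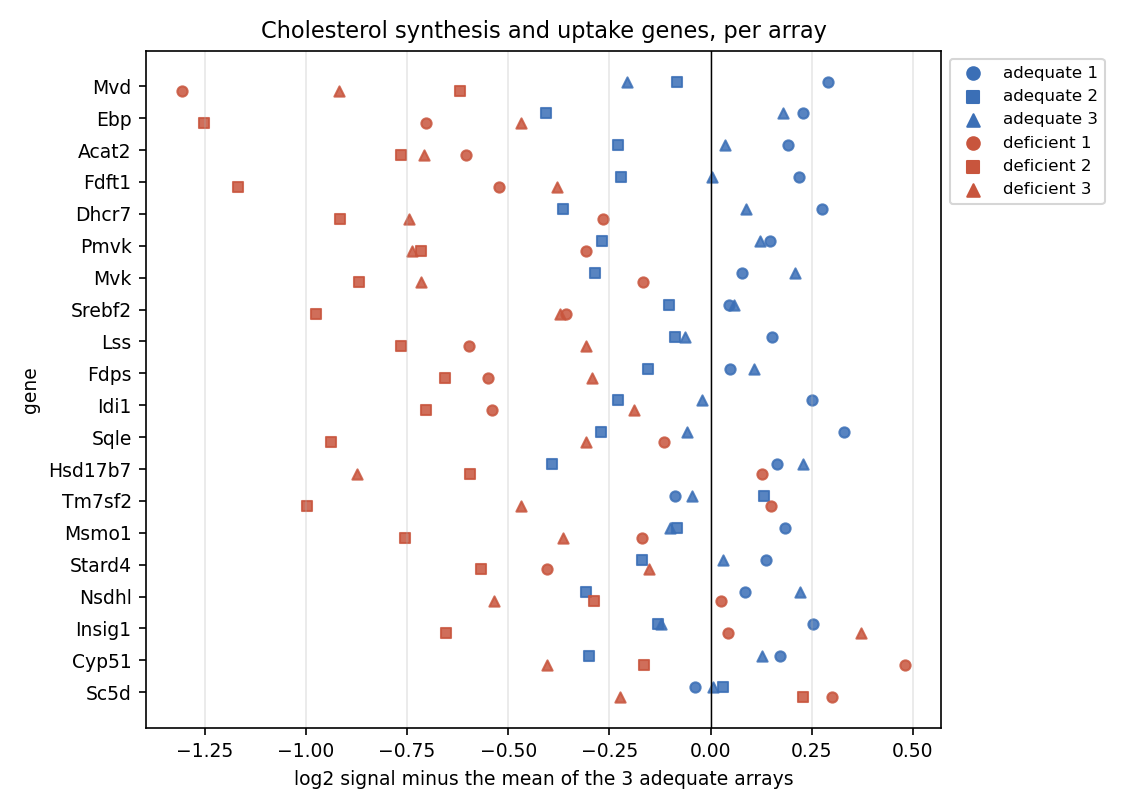
Log2 signal of the 20 tested cholesterol synthesis and uptake genes on each array, minus the mean of the 3 adequate arrays for that gene, with blue for adequate arrays, red for deficient arrays and a symbol per replicate number. For Acat2 and Mvd the 3 deficient arrays lie below the 3 adequate arrays, and for Sc5d deficient arrays 1 and 2 lie above them.

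Genes of hypoxia and glycolysis fell by a mean of 0.27 on the log2 scale, with 23 of 26 tested members lower. Ndrg1, a hypoxia-induced gene, had a log2 change of -0.58 ± 0.20 (SE), the hexokinase Hk1 -0.77 ± 0.29, the oxygen sensor Egln3 -0.43 ± 0.17 and the angiogenic factor Vegfa -0.42 ± 0.18. Of the members, 7 were lower at an unadjusted p under 0.05 and 0 passed adjusted over the list alone. The list passed camera with an adjusted p of 0.018, and had an adjusted p of 0.780 with an estimated correlation. Its mean was -0.21 and -0.47 on deficient arrays 1 and 2 and -0.12 on deficient array 3, with the adequate arrays between -0.03 and 0.03. Without deficient array 2 the adjusted p was 0.138, and without adequate array 3 it was 0.051. With the hybridisation controls as a covariate the mean was -0.11 (adjusted p 0.187), and with a term for deficient arrays 1 and 2 it was -0.12 (adjusted p 0.146).

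Lymphocyte markers fell by a mean of 0.59 on the log2 scale, with 10 of 11 tested members lower. The T cell receptor chain Cd247 had a log2 change of -0.94 ± 0.34 (SE), the invariant chain Cd74 -0.60 ± 0.22 and the B cell adaptor Blnk -0.51 ± 0.22. Cd3e read 7.57 in the adequate and 5.81 in the deficient group in log2 signal, the latter under the filter's cutoff of 6.46, so no fold is given. None passed adjusted over the list alone. The list passed camera with an adjusted p of 0.0397, and had an adjusted p of 0.780 with an estimated correlation. Its mean was -0.706 and -0.995 on deficient arrays 1 and 2 but -0.07 on deficient array 3, within the adequate arrays' range of -0.42 to 0.29. The call was lost without any 1 of 4 arrays: without adequate array 1 the adjusted p was 0.165, without adequate array 3 0.055, without deficient array 1 0.137 and without deficient array 2 0.130. It was also lost with no filter (0.131), the filter at the 60th percentile (0.147), the mean of a gene's probe sets (0.0629), a sex term (0.160), deficient array 3 alone (0.960), a term for deficient arrays 1 and 2 (0.973) and the hybridisation covariate (0.939), where the mean was -0.037.

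Smooth muscle markers rose by a mean of 0.24 and a median of 0.48 on the log2 scale, with 11 of 17 tested members higher and 6 lower. Synpo2, an actin-binding protein, had a log2 change of 0.62 ± 0.15 (SE) and was the only member past the threshold adjusted over the list alone. Of its 4 tested probe sets 2 were higher, and with the mean of a gene's probe sets 0 members passed in that way. The myosin light chain kinase Mylk had 0.85 ± 0.28, the myosin heavy chain Myh11 0.69 ± 0.24, with its other tested probe set lower, and the tropomyosin Tpm2 0.59 ± 0.21. The actin Acta2, 0.00 ± 0.20, and the desmin gene Des, -0.30 ± 0.20, were not higher. The list passed camera with an adjusted p of 0.00655, and had an adjusted p of 0.780 with an estimated correlation. Its mean was 0.35 and 0.27 on deficient arrays 1 and 2 and 0.08 on deficient array 3, within the adequate arrays' range of -0.09 to 0.14. After quantile normalization the mean was -0.025, the median 0.034 and the adjusted p 0.396. The mean was 0.08 with a term for deficient arrays 1 and 2 (adjusted p 0.0896) or with deficient array 3 alone (0.0932), and 0.09 with the hybridisation covariate, where the list passed (0.0205).

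**Figure D3:**
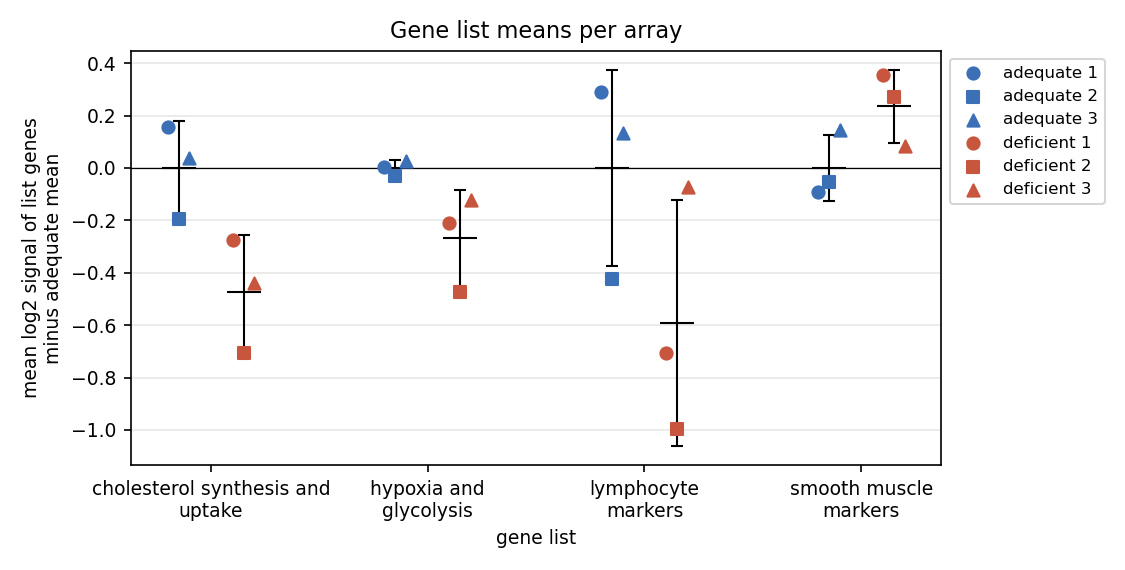
Mean log2 signal of the tested genes of the 4 lists past the camera threshold, relative to the mean of the adequate arrays, with 1 point per array, blue for adequate and red for deficient, and a symbol per replicate number. Horizontal ticks are group means and bars are SDs over 3 arrays. Deficient array 3 lies at -0.44 for cholesterol genes, below the adequate arrays, and at -0.07 for lymphocyte markers and 0.08 for smooth muscle markers, among them.

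Genes of the fat cell itself did not pass camera as groups. List means also did not overlap between the groups for the mature adipocyte, fatty acid synthesis, cell cycle, unfolded protein response, neutrophil and endothelial lists. By least squares on the list mean per array, the unadjusted p was smallest for neutrophil markers, at 0.010. It was 0.021 for endothelial markers, 0.033 for cell cycle, 0.039 for mature adipocyte and 0.044 for cholesterol genes. For the hypoxia list it was 0.066, for the smooth muscle list 0.096 and for the lymphocyte list 0.164. These p were not adjusted over the 32 lists. In the list of mature adipocyte and lipid storage genes, 12 of 17 tested members were lower, with a median log2 change of -0.25 and an adjusted p of 0.375, and Dgat2, which makes triglyceride, had -0.44 ± 0.21 (SE). Fatty acid synthesis had a median of -0.24 (adjusted p 0.515), with the citrate carrier Slc25a1 at -0.69 ± 0.24. Fatty acid oxidation had 19 of 21 members lower and a median of -0.30 (adjusted p 0.0683), with Hadha at -0.49 ± 0.20. Its mean was 0.05 on deficient array 3 and -0.34 and -0.46 on the other deficient arrays, and had an adjusted p of 0.00836 without deficient array 3. Adipogenic transcription factors had a median of 0.03 (adjusted p 0.188). In that list, Tcf7l1, at 1.01 ± 0.26, passed adjusted over the list alone, but its other tested probe set was lower, and with the mean of a gene's probe sets 0 members passed. The brown and beige adipocyte list had an adjusted p of 0.621, and Ppargc1b, a coactivator of mitochondrial genes, passed adjusted over it alone, at 0.80 ± 0.21. No member did when any 1 of the adequate arrays, deficient array 1 or deficient array 2 was left out. The median of that list was 0.09 and its mean was -0.02.

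Of the 12 genes fixed by name, 6 were tested and none had an adjusted p under 0.05. The preadipocyte gene Dlk1 was at 10.68 ± 0.16 in the adequate and 10.34 ± 0.20 (SD, n = 3 each) in the deficient group, in log2 signal. Fabp4 (-0.12 ± 0.21, SE), Fasn (-0.16 ± 0.21), Cebpa (0.00 ± 0.36), Igf1 (0.01 ± 0.15) and Srebf1 (0.16 ± 0.17) differed by less than their standard errors or by about as much. Adipoq, Cyp27b1, Lep, Pparg, Ucp1 and the vitamin D receptor gene Vdr were below the filter on dim probe sets and were not tested. Vdr read 4.41 ± 0.04 in the adequate and 4.76 ± 1.14 (SD, n = 3 each) in the deficient group in log2 signal, where only deficient array 1, at 6.07, was high, and Lep 1.68 ± 0.08 and 2.30 ± 0.70. Pparg read 6.28 ± 0.28 (SD, n = 3) in the adequate group and 6.23, 2.43 and 6.15 on the deficient arrays, so only deficient array 2 was low. The list of vitamin D metabolism and classical targets had 8 of 12 tested members higher, a median of 0.09 and an adjusted p of 0.169, with the sodium-calcium exchanger Slc8a1 at 0.33 ± 0.15 (SE). Its mean was 0.075, and -0.11 over 20 members without the filter on dim probe sets.

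The other pathway lists had adjusted p between 0.133 and 0.946. Extracellular matrix genes had 21 of 34 members higher (adjusted p 0.133), although Eln, the elastin gene, was at -0.87 ± 0.24 (SE). The adjusted p of that list was 0.0175 with array weights and 0.0170 without deficient array 3, and its mean was -0.14 after quantile normalization, against 0.09. Cell cycle genes had 21 of 30 members lower (adjusted p 0.375), with Cenpf at -0.47 ± 0.16. Immediate early and handling response genes had 14 of 20 lower (adjusted p 0.452). Dusp1, a phosphatase gene, at -1.05 ± 0.23, and Zfp36, at -0.83 ± 0.23, passed adjusted over that list alone, and Dusp1 also did in the glucocorticoid-responsive list (adjusted p 0.777). In neither list did a member pass in that way without adequate array 1, adequate array 2 or deficient array 1. In insulin and insulin-like growth factor signalling (adjusted p 0.946), Gys1, the muscle-type glycogen synthase, passed adjusted over the list alone, at -0.99 ± 0.24. No member did after quantile normalization, nor without adequate array 1, adequate array 3 or deficient array 2. Adjusted p was 0.375 for the unfolded protein response, with Atf3 at -0.54 ± 0.24, 0.452 for inflammatory cytokines and NF-kB targets, with Birc3 at -0.42 ± 0.20, and 0.406 for the interferon response, with Stat2 at -0.49 ± 0.23. It was 0.621 for oxidative phosphorylation subunits, with Cox7c at 0.44 ± 0.16, and 0.621 for the circadian clock, with Dbp at -0.77 ± 0.24. Camera, which sets a list against all other genes, gave the direction as higher in the insulin, oxidative phosphorylation, circadian and brown adipocyte lists, whose mean change was below 0. The interferon list had a median of -0.02 and a mean of 0.04.

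Markers of other cell types were tested because dissected mesentery can hold them. Macrophage markers had 11 of 14 members lower (adjusted p 0.169), with Tyrobp at -1.11 ± 0.39 (SE), and mast cell markers 10 of 12 lower (adjusted p 0.349), with Tpsab1 at -0.80 ± 0.30. The macrophage mean was -0.50 and -0.37 on deficient arrays 1 and 2, and the mast cell mean -0.60 and -0.55. On deficient array 3 these means were 0.02 and -0.02, within the range of the adequate arrays. Endothelial markers had 10 of 15 lower (adjusted p 0.188), with Tie1 at -0.74 ± 0.20, and neutrophil markers 5 of 6 lower (adjusted p 0.375), with Np4 at -0.86 ± 0.33. Hepatocyte markers had 10 of 10 lower (adjusted p 0.169), with Rbp4 at -0.53 ± 0.23, and intestinal epithelium markers 7 of 7 lower (adjusted p 0.169), with Anpep at -0.53 ± 0.22. In the last pair of lists adequate array 3 lay at 1.16 and 1.30 above the adequate mean and every other array below it. Adjusted p was 0.836 for fibroblast and adipose progenitor markers, with Thy1 at -0.92 ± 0.26, 0.946 for erythroid, with Alas2 at -0.59 ± 0.23, and 0.955 for mesothelial markers, with Krt18 at -0.58 ± 0.28; for the fibroblast and mesothelial lists camera gave the direction as higher and the mean was below 0. It was 0.967 for skeletal muscle, with Eno3 at -0.63 ± 0.22, 0.895 for nerve and glia, with Gap43 at 0.49 ± 0.18, and 0.461 for pancreas markers, with Cela1 at 7.49 in the adequate and 6.14 in the deficient group in log2 signal, the latter under the cutoff. Adrenal and kidney markers had 1 tested member, Lrp2 at 0.04 ± 0.24, and Y-linked genes 2, Uty and Eif2s3y, too few to test as lists.

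Among the single genes with the smallest unadjusted p and no overlap between groups, none passed, each with an adjusted p of 0.344. Higher in the deficient arrays were Ptprb, an endothelial phosphatase, at 8.55 ± 0.11 in the adequate and 9.62 ± 0.28 (SD, n = 3 each) in the deficient group in log2 signal, a fold of 2.10, and Nr2c1, an orphan nuclear receptor, with an adequate mean of 6.14. The other higher genes were Esf1, Setd5, Dyrk2, Ckap4, Psme4, Ube3c, Cobll1, Zdhhc20, Naa15 and Gnl3, at folds between 1.61 and 2.53. Lower were Gpatch11, at 7.25 ± 0.29 and 5.71 ± 0.11 (SD, n = 3 each), Dxo, a decapping enzyme, at 8.13 and 5.99, and Cryzl1-ps1, at 7.60 and 6.31. For these 3 and Nr2c1 no fold is given, since the dimmer group's mean lies under the filter's cutoff of 6.46. Irf8, a transcription factor of myeloid cells, had a log2 change of -0.88 ± 0.18 (SE), and Tafazzin, which remodels the mitochondrial lipid cardiolipin, -0.95 ± 0.20. The other lower genes were Six5, Obsl1, Dusp1, Sh3bgrl3, Nmral1, Hacd3 and Sms, at folds between 0.482 and 0.618. Other tested probe sets of the same gene disagreed in sign for Nr2c1, Setd5, Psme4, Ube3c, Ckap4, Gpatch11 and Sms.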

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

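The tests of the paired deficient arrays, of the cholesterol genes and of the smooth muscle genes were chosen only after these patterns were seen, and the regroupings of the arrays were planned. With values known, the bound for the smooth muscle cells was loosened for a time and then set back, and those for gene length and a single adequate array were changed to the spread between arrays, because camera also gave this list small p in regroupings that mixed the diets. The design names no biological grouping other than the dams' diet, and groups of 3 arrays are too small to test for outlying samples.

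Control probe sets outside the comparison read above every adequate array on deficient arrays 1 and 2. The bacterial hybridisation controls were 7.19 and 10.1 times the adequate mean, and the poly-A controls, which are added before labelling, 2.48 and 2.58 times. On the same arrays genes such as Gosr1, with a log2 change of 3.47 on these arrays and -0.07 on deficient array 3, and Ctnnb1, with 2.11 and 0.03, stood far from the adequate arrays. Maternal diet alone cannot be told apart from a technical difference of the pair: over the 3614 probe sets that passed without deficient array 3, the slope of that array's change on the pair's change was at most 0.0968, but it is 1 array, and the probe sets were chosen for the pair's change. Less labelled sample RNA may account for the pattern, since the lower of the pair exceeded the highest adequate array 6.09-fold in hybridisation controls. So may a stronger 3' bias, with the lower beta-actin 3' over 5' ratio 1.41 times the highest adequate ratio. The Gapdh 3' over 5' ratio gives less for it, at 1.71 and 1.36 on the pair against at most 1.30 on the adequate arrays. The log2 Gapdh 3' over middle ratio of deficient array 1, 0.603, lay below the lowest adequate array, at 0.608. A difference in litter, dissection or handling of these animals stays open as untested, and diet can act on top of any of these.

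The cholesterol synthesis and uptake list was lower in the deficient group. No technical explanation tested is excluded, and diet is not separated from differences between litters. A trend with gene length stays open. After its removal the list mean was -0.36 ± 0.15 (SE between arrays), against -0.47 ± 0.16 before. The median change of all genes also moved, from -0.09 to -0.01, so part of that drop is not particular to the list. Relative to all genes, the list mean shrank by less than the outcome named for this cause. With 3 arrays per group the rest is not clear of its spread. A single adequate array stays open too. The mean was -0.40 ± 0.18 without adequate array 1, -0.57 ± 0.17 without adequate array 2 and -0.45 ± 0.21 without adequate array 3. It shrank by less than the outcome named for this cause, but without adequate array 1 or 3 it was not clear of its spread. Over the list alone, 0 instead of 9 members passed without adequate array 1, and the same held without adequate array 3 or deficient array 2. Whether the list is low because of deficient arrays 1 and 2 cannot be told apart from diet. The mean was -0.44 ± 0.27 with a term for the pair and -0.38 ± 0.25 with the hybridisation covariate. Deficient array 3, at -0.44, carries the first and has a weight of 0.947 in the other. It lay below the lowest adequate array, at -0.20, by more than the adequate arrays' SD of 0.18. That was the outcome named for a cause other than the pair. The test still could not exclude the pair, since 1 array excludes nothing.

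The smooth muscle list was higher in the deficient group with the deposited scaling. After quantile normalization its mean was -0.025 ± 0.091 (SE between arrays), so the rise depends on how the arrays are scaled. The interquartile range of log2 signal was 3.53 and 3.71 on deficient arrays 1 and 2, 4.06 on deficient array 3 and 4.01 to 4.20 on the adequate arrays. More smooth muscle cells in the dissected tissue stay open as a cause. Without deficient array 3, 9 of the 17 list members passed the adjusted threshold in the higher direction, with Mylk at 1.20 ± 0.12 (log2, SE). In the lower direction 2 passed, Smtn at -0.64 ± 0.17 and Des at -0.48 ± 0.13, and Acta2 was at -0.11 ± 0.17. Smtn and Des met the bound named against more smooth muscle cells, which was 2 or more lower members. The lower members still cannot decide on cell content, since of all 18625 probe sets 1985 passed lower in that fit and 1629 higher. More such cells together with a technical shift of these arrays stay open. The pair of arrays with high controls may account for it, since the list mean of deficient array 3 was 0.082, among the adequate arrays. Diet stays open, since a single array without the change excludes nothing.

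With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For probe sets past the adjusted threshold, 10 of the 10 splits gave as many as the real count of 0, and the highest of the others was 0. Since no split can give fewer than 0, this comparison decides nothing. For probe sets at an unadjusted p under 0.05, 2 splits gave as many, with 2647 in the real split and 3174 in the highest other, which sets adequate arrays 1 and 3 and deficient array 3 against the 3 arrays with the highest beta-actin 3' over 5' ratios (7.56, 6.80 and 4.81). For gene lists past the threshold, 9 splits gave as many, with 4 in the real split and 8 in the highest other. For the cholesterol list, 2 splits gave as large a -log10 camera p, with 5.73 in the real split and 9.08 in the highest other, which sets adequate arrays 1 and 3 and deficient array 1 against the rest.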

How the results depend on the processing

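The settings with deficient array 3 alone, the pair term, the hybridisation control covariate, the sex term and the length correction were chosen after seeing the data; the others were planned. The pair, covariate and sex terms were first set aside as near-duplicates once their results were known, and are reported here. For a list, turned means here that camera's direction, which is relative to all other genes, changed; of 70 such values the list's own mean kept its sign in 49 and changed sign in 21. Limits: 3 arrays per group, no detection calls, and signals close to the filter carry little information. The cholesterol list passed in every setting run except the estimated correlation, with adjusted p from 3.52e-08 to 0.017, and the causes of the changes below were not tested. Whether the replicate numbers pair the arrays is not settled. Same-numbered arrays had correlations of deviations of 0.107, 0.153 and 0.00655, for each deficient array the highest with any adequate array. Adequate array 3, however, correlated better with deficient array 1 (0.0512) than with its own number. The SE between arrays of the cholesterol list mean was 0.023 with the block, on 2 residual degrees of freedom, against 0.163 on 4 without it. With the replicate block, 0 probe sets passed, 3235 had an unadjusted p under 0.05, 5 lists passed (fatty acid oxidation was added) and 31 list members passed over the list alone; insulin signalling and skeletal muscle markers turned, both at an adjusted p of 0.980 and with an unchanged mean, since the block leaves the log2 changes as they are.

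Leaving out each array in turn gave 0 to 3614 probe sets past the threshold, 906 to 6572 at an unadjusted p under 0.05, 2 to 8 lists and 3 to 187 list members. Only deficient array 3 gave calls when left out. Adjusted p ranged from 0.00313 to 0.138 for hypoxia and glycolysis, 0.00129 to 0.165 for lymphocyte markers, 0.00151 to 0.727 for hepatocyte markers, 0.522 to 0.976 for insulin signalling, 0.113 to 0.982 for inflammatory cytokines, 0.209 to 0.966 for immediate early genes, 0.316 to 0.952 for glucocorticoid-responsive genes, 0.198 to 0.982 for the circadian clock, 0.409 to 0.965 for erythroid, 0.361 to 0.982 for mesothelial, 0.799 to 0.976 for skeletal muscle, 0.638 to 0.984 for nerve and glia, and 0.388 to 0.954 for fibroblast markers. Log2 changes ranged from -0.43 to 0.25 for Cebpa, -0.33 to 0.085 for Fabp4, -0.35 to 0.068 for Fasn, -0.069 to 0.067 for Igf1, -0.11 to 0.19 for Acta2, -0.10 to 0.21 for Lrp2 and -0.55 to 3.68 for Eif2s3y.

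With array weights, which gave deficient array 3 a weight of 0.262, 3462 probe sets passed, 6678 had an unadjusted p under 0.05 and 177 list members passed; mesothelial (adjusted p 0.830) and skeletal muscle markers (0.931) turned, and Acta2 changed sign (-0.010). Quantile normalization left 5 list members; smooth muscle markers had 0.396, and oxidative phosphorylation (0.0949), insulin signalling (0.564), extracellular matrix (0.226), and fibroblast markers (0.400) turned, and Igf1 (-0.038) and Acta2 (-0.093) changed sign. Without a filter, lymphocyte markers had 0.131, and insulin signalling (0.947), mesothelial (0.904), pancreas (0.522), skeletal muscle (0.947) and fibroblast markers (0.954) turned. With the filter at the 60th percentile, lymphocyte markers had 0.147, and the interferon response (0.932), neutrophil (0.967) and skeletal muscle markers (0.932) turned. Skeletal muscle markers also turned with the offset (0.999). Without a trend 6 list members passed. With an estimated correlation 0 lists passed, and the 4 lists each had an adjusted p of 0.780. With the mean of a gene's probe sets, lymphocyte markers had 0.0629, and mesothelial (0.940) and skeletal muscle markers (0.959) turned. With the length trend removed 3 list members passed, and insulin signalling (0.855) and skeletal muscle markers (0.975) turned.

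With deficient array 3 alone, where the spread comes from the adequate arrays and the lone array is assumed to vary like them, 1214 probe sets had an unadjusted p under 0.05 and 8 list members passed; hypoxia had 0.126, lymphocyte markers 0.960 and smooth muscle markers 0.0932. Turned were adipogenic factors (0.225), mature adipocyte genes (0.960), fatty acid oxidation (0.323), extracellular matrix (0.857), interferon response (0.726), macrophage (0.616), nerve (0.989) and fibroblast markers (0.399). The sign changed for Cebpa (-0.36), Fabp4 (0.31), Igf1 (-0.10), Sc5d (-0.22), Tpsab1 (0.031), Des (0.071), Lrp2 (-0.30), and the Gapdh (-0.14) and beta-actin (-0.40) 3' over 5' differences. The pair term gave the same gene values, 1072 probe sets and 10 list members; hypoxia had 0.146, lymphocyte markers 0.973 and smooth muscle markers 0.0896, and adipogenic factors (0.247), fatty acid oxidation (0.325), extracellular matrix (0.868), interferon response (0.749), macrophage (0.749), nerve (0.992) and fibroblast markers (0.491) turned. With the hybridisation covariate there were 788 probe sets and 8 list members; hypoxia had 0.187, and lymphocyte (0.939), mast cell (0.939), macrophage (0.866), erythroid (0.866) and fibroblast markers (0.419), adipogenic factors (0.358), fatty acid oxidation (0.419), extracellular matrix (0.649), and the interferon response (0.939) turned. The sign changed for Cebpa (-0.27), Fabp4 (0.27), Igf1 (-0.088), Sc5d (-0.20), Des (0.039) and Lrp2 (-0.21). The sex term repeats the log2 changes found without adequate array 1, so these settings are not separate checks. With the sex term there were 1063 probe sets and 2 list members; lymphocyte markers had 0.160, and insulin signalling (0.967), inflammatory cytokines (0.979), circadian clock (0.979), erythroid (0.610) and fibroblast markers (0.950) turned, and Cebpa (-0.11), Acta2 (-0.11) and Eif2s3y (-0.55) changed sign. The Gapdh difference was -0.012 as a 3' over middle ratio.

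The mean itself changed sign for extracellular matrix with quantile normalization (0.09 to -0.14), pancreas markers without a filter (-0.45 to 0.17), the interferon response (0.037 to -0.12) and skeletal muscle markers (-0.066 to 0.011) at the 60th percentile, skeletal muscle markers with the length trend removed (0.043), and erythroid markers without adequate replicate 1 and with the sex term (-0.13 to 0.023). It also did for adipogenic factors, fatty acid oxidation, extracellular matrix and the interferon response with deficient array 3 alone, the pair term and the covariate, and for macrophage markers in the first 2 of these. The mean of every other turned list kept its sign. With camera's direction kept, the mean changed sign in 26 further values. These include smooth muscle markers after quantile normalization (-0.025) and the vitamin D list without a filter (-0.11 over 20 members, against 0.075), and the others were in lists with a mean between -0.06 and 0.07 as reported.

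Lists outside the 4 also passed in some settings. Fatty acid oxidation had an adjusted p of 0.00980 with array weights, 0.048 with the block, 0.045 without adequate replicate 2 and 0.00836 without deficient replicate 3. Extracellular matrix had 0.0175 with weights and 0.0170 without deficient replicate 3, where adipogenic factors (0.0468) and macrophage markers (0.0455) also passed. Intestinal and hepatocyte markers passed without adequate replicate 1 (0.0174 and 0.00151), without adequate replicate 2 (0.0197 and 0.0362), with the covariate (0.00411 and 0.0205) and with the sex term (0.018 and 0.00165), and intestinal markers with deficient array 3 alone (0.040) and the pair term (0.0218). Mast cell markers passed without adequate replicate 2 (0.0473). Immediate early genes and neutrophil markers passed with deficient array 3 alone (0.038 and 0.040), the pair term (0.0114 and 0.0212) and the covariate (0.017 and 0.00868).

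Of the named genes' values over all settings, 39 changed sign, 1420 kept their direction without passing and 123 passed in the same direction. The genes followed were narrowed to those named after a wider choice of 156 had been run, in which 73 of 2931 values changed sign.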

Other observations

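Adequate array 3 carried transcripts of liver and gut above the other adequate arrays. The urea cycle enzyme Cps1 was 3.49 higher on the log2 scale than the mean of the other adequate arrays, Ahsg 2.25 and Alb, the albumin gene, 2.14, and among gut epithelial genes Epcam was 3.34 higher. Lgals4 read 10.4 and Cdh17 9.33 on this array, and on the other adequate arrays their mean lay under the filter's cutoff of 6.46, so no difference is given. The albumin signal was 11.95 on this array, 9.40 and 10.23 on the other adequate arrays, and 10.94, 9.33 and 9.96 on the deficient arrays. Rbp4 and the endocrine marker Chga were not higher on this array, at -0.03 and -0.10. These genes were chosen after their values were seen, from lists written before the data were examined.

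The Y-linked gene Eif2s3y had a log2 signal of 3.20 on adequate array 1 and between 10.8 and 11.7 on the other 5 arrays. The labels give no sex. The only array without this signal was in the adequate group, so Y-linked signal was not balanced between the diets.

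On deficient array 3 the immediate early gene Egr1 lay at -1.39 on the log2 scale against the adequate mean, where deficient arrays 1 and 2 had 0.21. Egr2 lay at -1.46 against 0.06 and Fos at -0.94 against 0.64, while Dusp1 was low on both, at -1.29 and -0.94, and Hspa1a was higher on deficient array 3, at 0.91 against -0.18. These are values of 1 array, and the genes were chosen after their values were seen.

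The log2 change of a gene against the adequate mean followed its genomic length on the same pair of arrays. Across 10561 genes, which are not independent replicates, Spearman's rho was 0.164 on deficient array 1, 0.181 on deficient array 2 and 0.00783 on deficient array 3, and between -0.0445 and 0.0397 on the adequate arrays.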
